A study of Mus musculus with 12 samples.

How the data were processed

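RNA was measured by poly(A) sequencing in 12 Lewis lung carcinoma tumours, in 4 groups of 3 mice: control, MEKi (trametinib), RT (radiation) and RT+MEKi. Per the labels' protocols, tumour blocks away from necrosis were taken, so each library mixes tumour cells with the stroma, immune cells and adjacent tissue in its block. The groups and replicate numbers came from the sample labels. The labels also give the source tissue as colon cancer, in conflict with their titles, cell line and protocols, and the cell line is followed here.

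The deposited table gives estimated counts per gene and library, per the file headers, and 88.0% to 90.5% of its values in each library are whole numbers. The authors also deposited FPKM values, per the file headers, which scale the counts by transcript length and depth. For each treatment against control the authors' deposited table holds log2 fold changes, together with p-values and q-values from DESeq2, per the file headers, with no version named. The gene coordinates and NCBI gene IDs are those of the deposited table. The aligner, the counter and the genome build are not given in the sources used here. Of the 18147 genes, 18096 matched a RefSeq table of assembly GRCm38.p6 by gene ID, 17997 of them on the same chromosome, and 84.9% of the start positions were identical. Nothing in the sources says whether counting used strand, so reads of overlapping genes on opposite strands may not have been told apart. Another 12 columns of values per library were not used here.

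Total counts per library were 17205444, 17346116 and 17660483 in control replicates 1 to 3 and 15421995, 17083704 and 14416880 with MEKi. They were 17663716, 17151966 and 16486598 with RT and 15129884, 16549443 and 17542301 with RT+MEKi. A chi-square comparison of replicate pairs gave 9.71 to 46.4 per degree of freedom, so no 2 libraries of a group agreed within sampling noise.

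Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the groups, TMM scaling, and a quasi-likelihood fit of all 12 libraries with 1 coefficient per group and 8 residual degrees of freedom. That kept 13562 genes. The 6 contrasts were each treatment against control, RT+MEKi against RT, RT+MEKi against MEKi, and the interaction (RT+MEKi minus RT minus MEKi plus control). P-values were adjusted by Benjamini-Hochberg, and a gene changed where the adjusted p was at or below 0.05. The SE of a log2 fold change is its unshrunk size divided by the square root of the F statistic. Values in CPM are counts divided by TMM-scaled library totals and are given as mean ± SD over 3 tumours. A single-gene exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so the adjusted p rests on a spread shared across genes.

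Gene lists were tested with camera in limma 3.58.1 on the same fit, with a preset correlation of 0.01, and again with an estimated correlation, with fry beside it as a test of whether a list's genes move on balance one way. Of 32 lists, 29 had at least 5 tested genes. Mast cells and eosinophils (4 tested), epidermis and hair (4 tested) and mitochondrially encoded genes (0 tested) were not analysed. Lists, comparisons and tests were chosen before the data were examined. Tested out of listed genes, the lists with losses were ERK output (19 of 20), receptor tyrosine kinases (14 of 15), type I interferon (22 of 24), interferon gamma (17 of 19), cGAS-STING (9 of 10) and chemokines (22 of 24). Likewise they were cytokines (24 of 26), T cells (18 of 20), cytotoxic lymphocytes (17 of 20), regulatory T cells (6 of 7), B and plasma cells (7 of 12), dendritic cells (12 of 14), p53 targets (23 of 24), fat (13 of 14) and red blood cells (7 of 10).

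The genes named in the text follow a rule fixed in advance. It takes 12 core genes of the study's question, namely Cd274, H2-K1, H2-D1, B2m, Cd3e, Cd4, Cd8a, Gzmb, Ifng, Dusp6, Mki67 and Cdkn1a. It adds the 6 largest rises and 6 largest falls past the threshold among genes with an average log2 CPM of at least 1 and groups that do not overlap, leaving out gene models without a proper name. Where none passes it adds the 2 smallest p-values. For each list it takes up to 4 members past the threshold over all genes, or else over the list alone, or else the 2 most expressed. Ifit2, Cox6c, Mxd4, Myc and the granzyme, haemoglobin and fat genes named below are picked by the rule in some comparison. Not every gene that the rule picks is named. Pvalb and the other genes of the KEGG terms in the closing observations lie outside the rule and were named after their values were seen.

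The steps were tested on simulated counts with 200 changed genes per comparison, 100 at each size. Changes of 1.5-fold and 2-fold were recovered in 13% and 68% of cases for MEKi against control over 13431 genes, 30% and 57% for RT against control over 13427 genes, and 30% and 69% for RT+MEKi against control over 13428 genes. False calls were 5 of 88, 7 of 95 and 3 of 103, and 0 of 28 unchanged lists were called in each. The simulated genes varied independently of each other and the unchanged lists were random genes. These counts therefore do not show how often lists of genes that vary together are falsely called. Other groupings of the real libraries of RT against control called up to 21 of 29 lists.

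Alternatives were DESeq2 size factors and library totals in place of TMM, no filter on low counts and a filter at a mean CPM of 5, and the replicate number as a block. Others were the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, a fit of only the 2 compared groups, and each library left out in turn. Chosen after seeing the data were fits without the 4 libraries richest in muscle transcripts, with marker list means as covariates (muscle and fat, macrophage, red blood cell), and with each library's trend with GC content and transcript length removed. KEGG terms came from the deposited annotation and were tested with a one-sided Fisher's exact test among the 5631 tested genes that carry a term, over 652 tests of terms with at least 10 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.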

Results

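The data were RNA-seq profiles of 12 Lewis lung carcinoma tumours, a mouse lung cancer line with a mutant Kras that was grown under the skin of the right flank of C57BL/6 mice. The tumours fell into 4 groups of 3, each tumour from a different mouse: untreated controls, trametinib alone (MEKi, an inhibitor of the kinase MEK, 1 mg/kg by daily gavage), radiation alone (RT, 8 Gy in 1 fraction), and both treatments together (RT+MEKi). Each library held between 14416880 and 17663716 estimated counts over 18147 protein-coding genes, of which 13562 were tested. The biological coefficient of variation over all genes was 0.219, and every group had n = 3.

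Markers of tissue next to the tumour differed widely between libraries. Skeletal muscle markers took 0.101% of the counts in MEKi replicate 1, 0.299% in MEKi replicate 3, 0.859% in RT replicate 2 and 0.257% in RT+MEKi replicate 1, and between 0.0127% and 0.0169% in the other 8 libraries. Fat markers took 0.0858%, 0.0882% and 0.0484% of the counts in the 3 RT+MEKi libraries against 0.0103% to 0.0141% in the controls, and 0.0741%, 0.0125% and 0.0309% in the MEKi libraries and 0.0696%, 0.0354% and 0.0115% in the RT libraries. Red blood cell transcripts took 0.358%, 0.431% and 0.146% of the counts in the controls and 0.411% in RT replicate 3, and between 0.0168% and 0.0937% in the other 8 libraries.

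**Figure D1:**
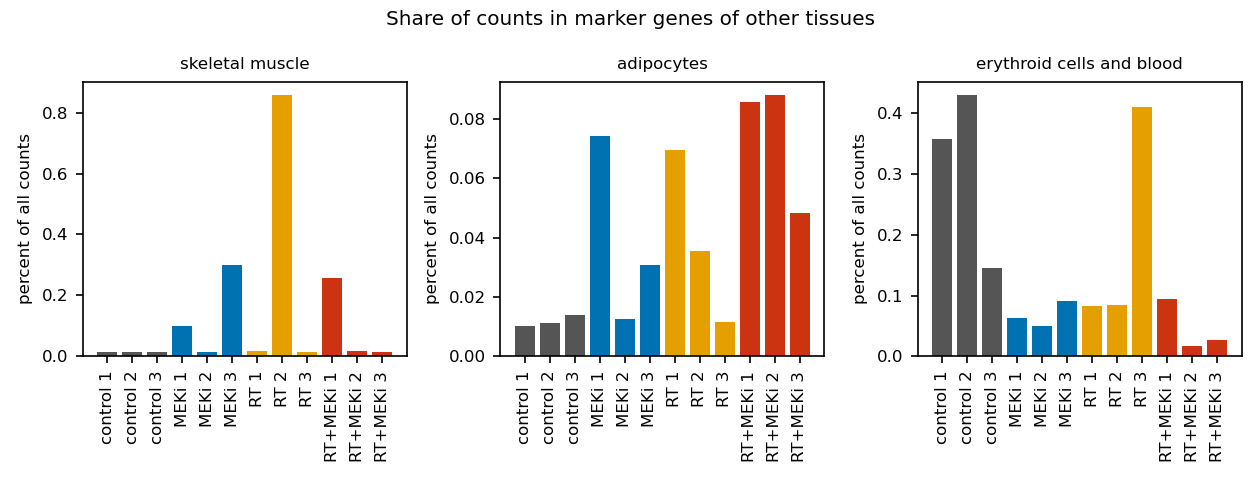
Percent of each library's counts taken by skeletal muscle, fat and red blood cell markers, with 1 bar per library grouped by treatment. The tallest muscle bar is RT replicate 2 at 0.859%, and the fat bars of the 3 RT+MEKi libraries lie above the control bars.

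The comparison of combined treatment with control asked how radiation and MEK inhibition together changed the tumours. It gave most of the changed genes, 180 higher and 248 lower in RT+MEKi out of 13562 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at or below 0.05), and genes induced by type I interferon rose together. Of the 22 tested genes of the type I interferon list, 16 rose in the test over all genes and 21 rose when adjusted over the list alone, and the mean log2 fold change of the list was 1.07 with an SD of 0.46 between its genes. Irf7, the transcription factor that amplifies the interferon response (gene ID 54123, chromosome 7, 141263183 to 141266499), rose from 25.7 ± 2.13 to 97.8 ± 8.96 CPM (counts scaled to library size, mean ± SD, n = 3). Its log2 fold change was 1.93 ± 0.27 (SE, adjusted p = 0.0199 by edgeR). Ifit3 (gene ID 15959, chromosome 19, 34583119 to 34588982) rose from 11.96 ± 3.23 to 48.4 ± 10.8 CPM. Ifit1 rose by 1.66 ± 0.22 on the log2 scale, and the interferon-stimulated protease Usp18 by 1.36 ± 0.31. Ifit3 and Ifit1 have close relatives in the same gene cluster that can share reads, so their single values are less certain. The mean log2 CPM of the list lay between 5.32 and 5.65 in the 3 RT+MEKi libraries and between 4.23 and 5.13 in the other 9. The list rose by limma camera with a preset correlation (adjusted p = 4.96e-34) and by limma fry (adjusted p = 0.0125), and had an adjusted p = 0.184 with an estimated correlation. It was the 1 list of 29 that passed by fry in this comparison, and by fry 0 lists passed in each of the other comparisons. In the same libraries the macrophage markers rose as well, with a mean log2 fold change of 0.77, and the fat markers rose while the red blood cell markers fell. Scaling to library totals in place of TMM gave 201 higher and 91 lower genes, so the balance of higher and lower genes depended on the scaling. With limma on log2(FPKM + 1), which also changes the test and the gene filter, 364 were higher and 153 lower. The number of changed genes fell to 0 without control replicate 1 or RT+MEKi replicate 1, to 3 without control replicate 2, to 4 without RT+MEKi replicate 2 or 3, to 0 without the 4 muscle-rich libraries, and rose to 692 without control replicate 3. It was 16 with the replicate number as a block, 268 without a filter on low counts, 822 in a fit of only these 2 groups and 717 with the GC and length trend removed, and DESeq2 called 1523 (724 higher, 799 lower). It was 0 with muscle and fat or macrophage covariates and 1 with the red cell covariate.

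**Figure D2:**
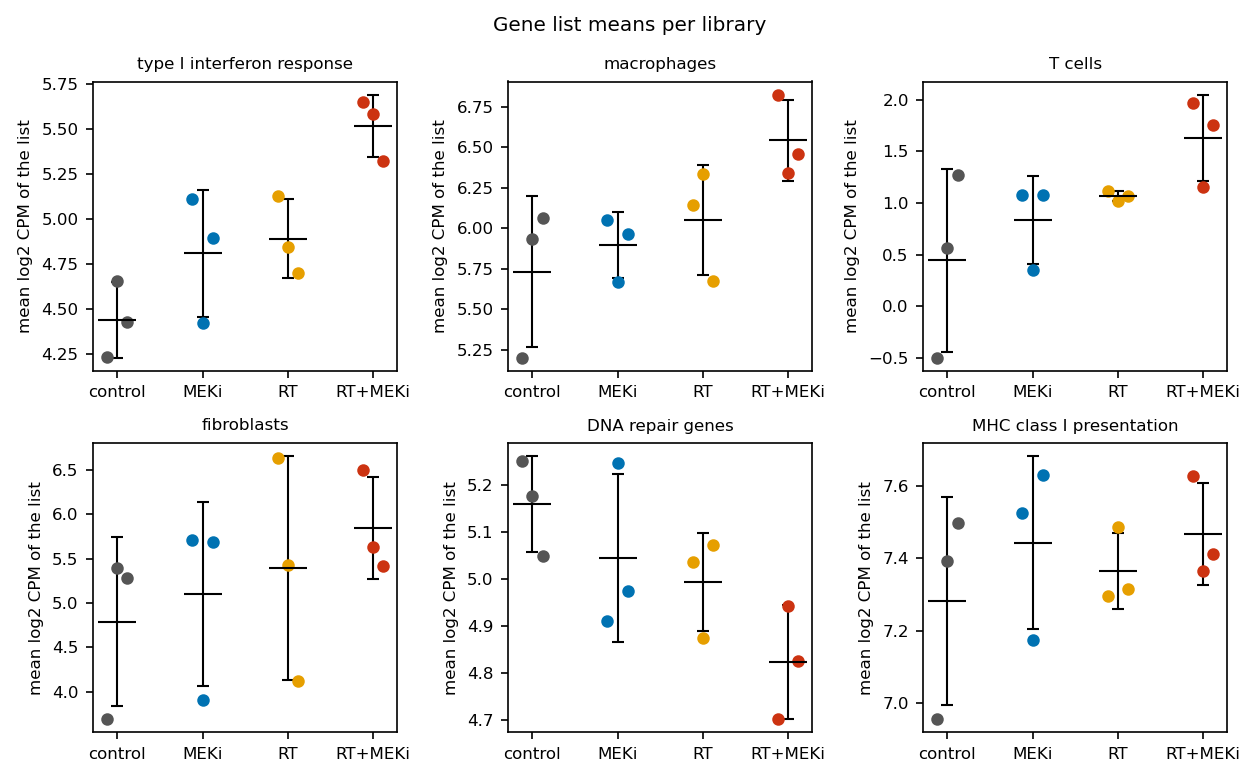
Mean log2 CPM of 6 gene lists in each of the 12 libraries, with 1 dot per library and the mean ± SD of each group (n = 3). For the type I interferon list the 3 RT+MEKi dots lie between 5.32 and 5.65, above the highest dot of the other groups at 5.13.

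Other immune genes followed in the same comparison of combined treatment with control. Of the 20 macrophage and monocyte markers 2 rose over all genes and 7 when adjusted over the list alone. They were led by the monocyte surface protein Ly6c2, which rose by 2.09 ± 0.34 on the log2 scale (SE, edgeR adjusted p = 0.0235) and can share reads with its neighbour Ly6c1. The monocyte chemokine receptor Ccr2 rose from 11.1 ± 1.92 to 32.9 ± 3.58 CPM. Of the 18 T cell markers 1 rose over all genes, the costimulatory receptor Icos (log2 fold change 1.49 ± 0.34), and 7 when adjusted over the list alone. Cd4 was at 1.69 ± 1.57 CPM in controls and 8.69 ± 1.29 CPM in RT+MEKi (log2 fold change 2.35 ± 0.62, edgeR adjusted p = 0.0617). Cxcl10, an interferon-induced chemokine, was the 1 of 17 interferon gamma genes that rose (1.35 ± 0.28). Ifi204, a DNA sensor with close paralogs, was the 1 of 9 genes of the cGAS-STING list (1.03 ± 0.21). Ccl11, which attracts eosinophils, was the 1 of 22 chemokines over all genes (3.02 ± 0.69). Adjusted over the list alone, the interferon gamma list again had 1 higher gene, the chemokines had 2, and the cGAS-STING list had 3 higher and 1 lower, while its camera adjusted p was 0.0537. Of the 16 checkpoint genes, Vsir (0.90 ± 0.18) and Lgals9 (0.79 ± 0.18) rose, which was the same count when adjusted over the list alone. Blk, a kinase of B cells, was the 1 of 7 B lineage genes that rose (3.44 ± 0.79), also when adjusted over the list alone, at a level of 0.914 ± 0.227 CPM, and the list had a camera adjusted p = 0.0537. By camera with a preset correlation the lists of T cells (adjusted p = 1.13e-07), macrophages (2.24e-09), interferon gamma (7.26e-05), checkpoints (0.0226), chemokines (0.0463), dendritic cells (0.0213) and MHC class I presentation (0.0388) rose. Their adjusted p with an estimated correlation lay between 0.399 and 0.631. In this comparison 17 lists changed, and 7 of 10 splits of its libraries, the real one included, called at least as many. With the macrophage markers as a covariate the lists of MHC class I (0.000123), interferon gamma (0.00896) and chemokines (0.0218) were lower instead. Checkpoints, at -0.16 relative to all other genes (0.661), and dendritic cells, at -0.014 (0.763), changed sign, and T cells lost their call (0.342). The macrophage markers were themselves higher in RT+MEKi by 0.81 with an SE of 0.27, and an estimated correlation was not run with any covariate. The lower calls of that fit are therefore uncertain. With muscle and fat covariates chemokines were at -0.28 (0.669), and the calls of interferon gamma (0.621), MHC class I (0.698), checkpoints (0.0651) and dendritic cells (0.280) ended. The red cell covariate ended those of MHC class I (0.0874) and checkpoints (0.0821) and turned dendritic cells to -0.16 (0.851). Without the 4 muscle-rich libraries MHC class I (0.197), chemokines (0.214) and dendritic cells (0.0555) lost theirs, and with the GC and length trend removed MHC class I and chemokines did (0.0808 each). Leaving out control replicate 1 ended the calls of MHC class I (adjusted p = 0.763), checkpoints (0.294), chemokines (0.47) and dendritic cells (0.0907). Leaving out RT+MEKi replicate 1 ended those of MHC class I (0.209) and chemokines (0.248), and leaving out RT+MEKi replicate 3 those of checkpoints (0.0775) and chemokines (0.0659). Each gene call named here was lost without control replicate 1 or RT+MEKi replicate 1, where 0 genes passed.

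Genes that the study's design centres on did not pass the test in this comparison. Cd274, which encodes PD-L1 (gene ID 60533, chromosome 19, 29362107 to 29388095), was at 20.9 ± 6.62 CPM in controls, 21.3 ± 6.03 with MEKi, 23.6 ± 6.81 with RT and 26.6 ± 9.30 with RT+MEKi (n = 3 each). Its log2 fold change of 0.35 ± 0.31 for RT+MEKi over control had an edgeR adjusted p = 0.504. The MHC class I heavy chains H2-K1 (0.03 ± 0.22) and H2-D1 (0.02 ± 0.18) and their light chain B2m (0.10 ± 0.19) had log2 fold changes within 1 SE of 0. Cd8a went from 4.90 ± 3.29 to 5.93 ± 2.87 CPM (0.27 ± 0.55), Cd3e had a log2 fold change of 0.57 ± 0.51, and the effector genes Gzmb (0.45 ± 0.26) and Ifng (0.98 ± 0.77) had edgeR adjusted p values of 0.308 and 0.436. Of 17 genes of cytotoxic lymphocytes 0 changed over all genes by edgeR, and the list had a camera adjusted p = 0.997. Adjusted over the list alone, 1 was higher and 5 were lower, among them the neighbouring granzymes Gzmc, Gzmd, Gzme and Gzmf, which are similar enough to share reads. Of the neutrophil markers 0 of 16 changed over all genes and 2 were lower when adjusted over the list alone, Retnlg (-2.71 ± 0.76) and Ly6g (-1.94 ± 0.55). MHC class II genes (0 of 11), cytokines (0 of 24) and regulatory T cell markers (0 of 6) had no member past the threshold on either adjustment, with camera adjusted p values of 0.0642, 0.0875 and 0.101.

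Some fibroblast and matrix genes rose after the combined treatment, and single genes of ERK output, DNA repair, DNA replication and stress response fell. The list calls of this paragraph, by camera with a preset correlation, were lost with an estimated one (adjusted p from 0.399 to 0.631). Of 20 fibroblast and matrix genes 4 rose over all genes, and 6 were higher and 1 lower when adjusted over the list alone. Lum, a matrix proteoglycan (gene ID 17022, chromosome 10, 97565501 to 97572703), rose from 17.68 ± 6.63 to 67.6 ± 7.71 CPM (log2 fold change 1.94 ± 0.27, edgeR adjusted p = 0.0199). With it rose Dpt (1.36 ± 0.31), the collagen gene Col5a1 (0.87 ± 0.19) and the growth factor receptor Pdgfra (0.54 ± 0.12). Pdgfra was also the 1 of 14 receptor tyrosine kinase genes that rose (1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.529). Among 19 transcripts that follow ERK activity, the transcription factors Etv4 (-0.55 ± 0.13) and Etv5 (-0.51 ± 0.12) fell, and 4 were lower when adjusted over the list alone. Dusp6, the ERK phosphatase, was at 178 ± 6.32 CPM in controls and 138 ± 20.9 in RT+MEKi (edgeR adjusted p = 0.142). Of 21 DNA repair genes all had a negative log2 fold change, 1 fell over all genes, the Fanconi anaemia gene Fanca (-0.56 ± 0.09), and 10 were lower when adjusted over the list alone. Of 22 DNA replication genes 1 fell, the cyclin gene Ccne2 (-0.81 ± 0.16), and 6 were lower when adjusted over the list alone. Asns, which makes asparagine and is induced by the integrated stress response, was the 1 of 18 stress response genes that fell (347 ± 92.4 to 146 ± 14.3 CPM), with 5 lower and 1 higher when adjusted over the list alone. With the red cell markers as a covariate the stress list was at 0.0041 relative to all other genes (camera adjusted p = 0.209). Of 23 p53 targets only Tnfrsf10b changed (-0.58 ± 0.13, edgeR, on either adjustment), and Cdkn1a, the p21 gene, had a log2 fold change of 0.20 ± 0.21. Mitotic genes (0 of 20, Mki67 at -0.01 ± 0.16), hypoxia and glycolysis genes (0 of 18) and cholesterol synthesis genes (0 of 18) had no changed member, and camera adjusted p values of 0.558, 0.961 and 0.967. By camera the fibroblast list rose (adjusted p = 3.77e-06), and the lists of ERK output (0.00943), DNA repair (1.77e-07), DNA replication (7.26e-05), stress response (0.00943) and endothelium (0.0213, with 0 of 17 genes changed on either adjustment) fell. The fat markers rose (5.05e-10), the red blood cell markers fell (1.01e-07) and the muscle markers rose (0.00757), though with the macrophage covariate they were lower (3.25e-06). An estimated correlation was not run with that covariate. Relative to all other genes the fibroblast list turned to -1.31 with muscle and fat covariates (0.142) and to -0.79 with the macrophage covariate (0.763). Endothelium turned to 0.24 with the macrophage covariate (0.192) and to 0.12 with the red cell covariate (0.106). The macrophage covariate also ended the calls of DNA repair (0.175), DNA replication (0.107) and stress response (0.763). The muscle and fat covariates ended those of ERK output (0.138), endothelium (0.669) and stress response (0.509), and the red cell covariate that of ERK output (0.808). Relative to all other genes ERK output was at -0.28, endothelium at -0.012 and stress response at -0.15 with muscle and fat covariates. With the red cell covariate ERK output was at -0.032. Without the 4 muscle-rich libraries the muscle call ended (0.147). The calls ended for ERK output (0.060) and stress response (0.0673) without control replicate 2, for endothelium without control replicate 1 (0.0746) or RT+MEKi replicate 3 (0.114), and for muscle without RT+MEKi replicate 1 (0.436). Each gene call named here was lost without control replicate 1 or RT+MEKi replicate 1, where 0 genes passed.

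The largest changes past the threshold included genes outside these lists. The largest rises among genes with a mean log2 CPM of at least 1 were of Cd5l, a protein secreted by macrophages (5.02 ± 1.23 on the log2 scale), Ccl11, Ms4a4c (2.64 ± 0.37), Prl2c2 (2.52 ± 0.58), the inflammasome gene Mefv (2.42 ± 0.29) and Ifit1bl1 (2.20 ± 0.34). Ms4a4c, Prl2c2 and Ifit1bl1 belong to families whose members can share reads. Aldh1l2, a mitochondrial enzyme of folate metabolism (gene ID 216188, chromosome 10, 83484956 to 83534146), had the largest fall, from 139 ± 67.4 to 17.9 ± 2.09 CPM (log2 fold change -2.96 ± 0.57, edgeR adjusted p = 0.0352). It was followed by Cth, which makes cysteine (-2.71 ± 0.58), Avil (-1.88 ± 0.35), Soat2 (-1.83 ± 0.39), Adh7 (-1.77 ± 0.35) and Pycr1, which makes proline (-1.71 ± 0.29). Their edgeR adjusted p values lay between 0.0151 and 0.0496, and each call was lost without control replicate 1 or RT+MEKi replicate 1, where 0 genes passed. Over all genes 35.1% had groups that did not overlap, against 10% by chance for 3 against 3. The authors' deposited table called 1742 genes in this comparison, 847 higher and 895 lower, and 419 of the 428 genes were among them, with all 428 in the same direction. Fat transcripts were the other large difference. Adipoq, the adiponectin gene, was at 22.1 ± 7.29 CPM in RT+MEKi against 0.0583 ± 0.00225 in controls, where each library held 1 count (edgeR adjusted p = 0.0777), and Plin1 had 98, 85 and 34 counts in the RT+MEKi libraries and 0 in each control. Of the 13 fat markers 0 changed over all genes by edgeR and all 13 were higher when adjusted over the list alone. Haemoglobin gene Hba-a1 was at 138 ± 119 CPM against 1122 ± 554 (edgeR adjusted p = 0.0552, paralog Hba-a2 sharing reads), and all 7 red cell markers were lower when adjusted over the list alone.

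**Figure D3:**
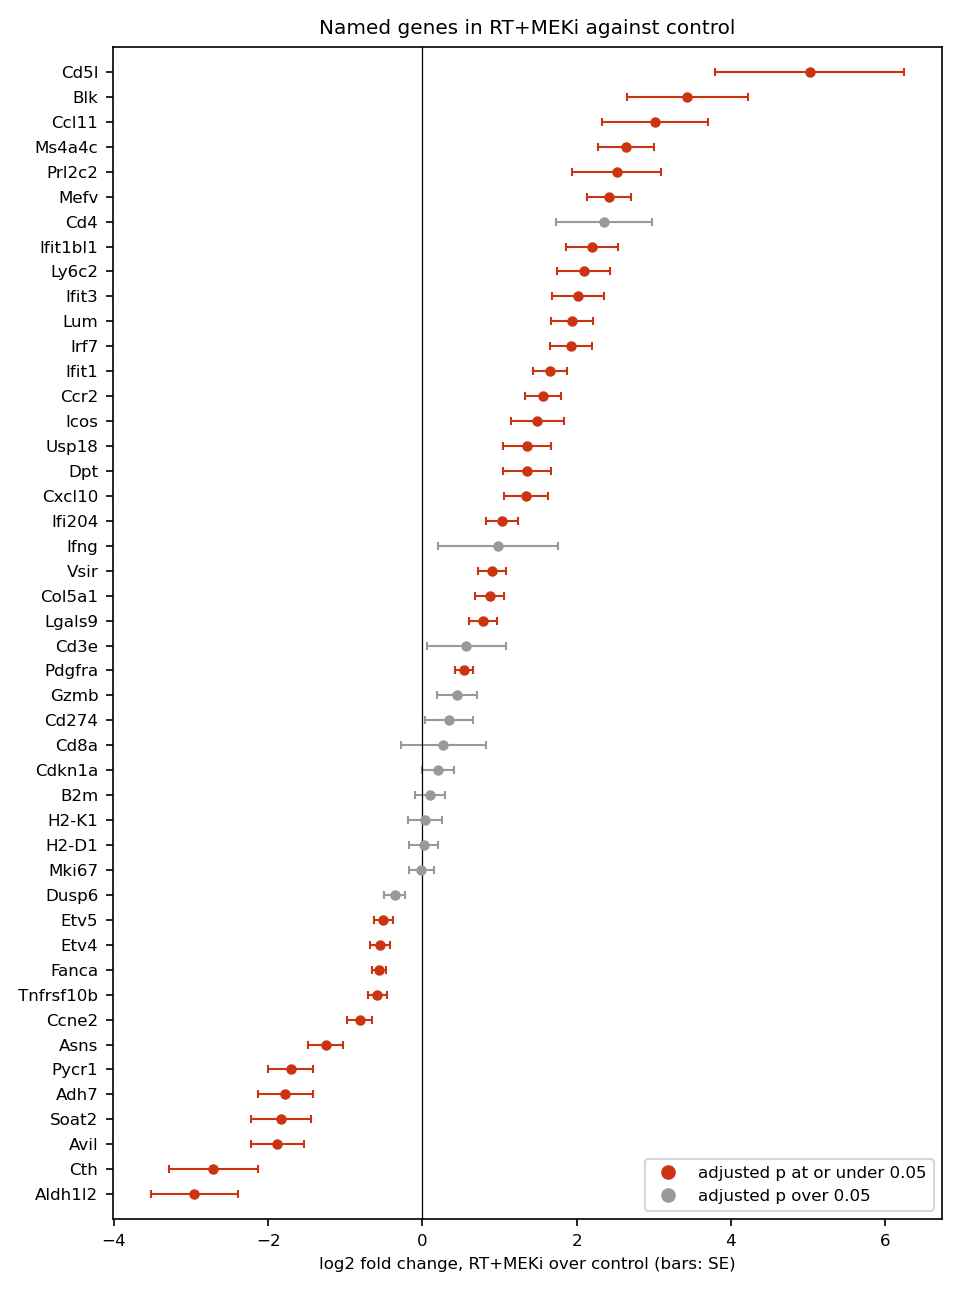
Log2 fold change of RT+MEKi over control for named genes, with bars of 1 SE from the edgeR fit (n = 3 tumours per group). Red marks genes with an adjusted p at or below 0.05, such as Irf7 at 1.93 and Aldh1l2 at -2.96, and Cd274 at 0.35 is not among them.

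Trametinib alone was compared with control to see the effect of the drug without radiation. Under the drug alone, transcripts that follow ERK activity fell as a list, with 15 of 19 below 0 and a mean log2 fold change of -0.17, and genes of cholesterol synthesis rose as a list, with 16 of 18 above 0 and a mean of 0.25. These calls and the next ones, by camera with a preset correlation, were lost with an estimated one (adjusted p from 0.746 to 0.814). With the red cell markers as a covariate cholesterol synthesis turned to -0.15 relative to all other genes (0.727), and ERK output lost its call (0.817). The mean log2 CPM of the ERK output list was 5.78, 6.17 and 5.71 in control replicates 1 to 3 and 5.80, 5.42 and 5.90 with MEKi. The size of its fall thus leaned on control replicate 2 and MEKi replicate 2. Type I interferon genes also rose as a list, with 21 of 22 above 0 and a mean of 0.38, as did interferon gamma genes (mean 0.30) and MHC class I presentation genes (0.15), while DNA replication (-0.12) and DNA repair genes (-0.11) fell. Relative to all other genes the type I interferon list was at 0.28. It was at 0.15 without MEKi replicate 1 and at 0.42 without MEKi replicate 2, and kept its call in both. Dusp6 went from 178 ± 6.32 to 145 ± 20.8 CPM (n = 3, log2 fold change -0.30 ± 0.14, edgeR adjusted p = 0.399), Myc had a log2 fold change of -0.62 ± 0.19 and Cd274 of 0.02 ± 0.31. Over all 13562 genes edgeR called 0, with 1772 at an unadjusted p below 0.05, and the nearest to the threshold was Cox6c, a subunit of cytochrome oxidase (0.72 ± 0.09, adjusted p = 0.0528). DESeq2 called 165 genes, 86 higher and 79 lower, and limma on FPKM called 1. The edgeR test called 1 without a filter on low counts and 1 without MEKi replicate 2. The authors' deposited table called 184, 108 higher and 76 lower. Adjusted over the list alone, the p53 target Zmat3 (-0.51 ± 0.10), 7 fat markers (higher) and 7 red cell markers (lower, among them Hbb-bt at -2.53 ± 0.79) passed, and 0 members did in each of the other lists. By camera with a preset correlation the adjusted p values were 5.25e-08 for type I interferon, 4.49e-05 for cholesterol synthesis, and 0.000528 for ERK output. They were 0.0127 for MHC class I and DNA replication, 0.0493 for interferon gamma and DNA repair, and 2.02e-09, 1.61e-07 and 2.4e-09 for muscle, fat and red cell markers. Leaving out control replicate 1 ended the calls of MHC class I (0.883), interferon gamma (0.883), DNA replication (0.261) and DNA repair (0.514). Leaving out MEKi replicate 1 ended MHC class I (0.0505) and DNA repair (0.488), and leaving out MEKi replicate 3 ended MHC class I (0.302), interferon gamma (0.998) and DNA repair (0.28). The number of changed lists was 10, and rose to 16 without control replicate 2 and to 18 without control replicate 3. Of 10 splits of these libraries, the real one included, 7 called at least 10 lists. Without the 4 muscle-rich libraries MEKi replicate 2 was the 1 MEKi library left, assumed to vary like the other groups, and it had the lowest interferon list means of its group. In that fit the type I interferon list had an adjusted p = 0.988, and the interferon gamma list was lower (0.0230). With muscle and fat marker covariates the type I interferon list had 0.863. Relative to all other genes MHC class I was at -0.038 (0.492) and DNA repair at 0.18 (0.143) without those libraries, and at -0.013 (0.863) and 0.12 (0.157) with those covariates. DNA replication lost its call in both (0.143 and 0.160), the fat markers theirs in the first (0.986), and interferon gamma (0.0658) and cholesterol synthesis (0.0519) theirs in the second. The macrophage covariate ended the calls of MHC class I and DNA replication (0.0634 each) and of interferon gamma and DNA repair (0.285 each). The red cell covariate also ended those of interferon gamma (0.0845), DNA repair (0.0831) and fat (0.0662), and removal of the GC and length trend those of interferon gamma (0.0502) and DNA repair (0.0740). With that trend removed these 2 lists were at 0.20 and -0.18 relative to all other genes.

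Radiation alone was compared with control to see its effect without the drug. The type I interferon list rose, with 21 of 22 genes above 0 and a mean log2 fold change of 0.45. This call and those of the other lists here, by camera with a preset correlation, were lost with an estimated one (adjusted p = 0.577 for each). All 10 splits of these libraries, the real one included, called at least the real 13 lists. The number of list calls therefore does not set the treatment apart from other groupings. Higher too were the lists of T cells (mean 0.48, 17 of 18 above 0), macrophages (0.33, 18 of 20) and fibroblast and matrix genes (0.85, 19 of 20). With muscle and fat covariates the fibroblast list turned to -0.61 relative to all other genes (adjusted p = 0.737) and macrophages had 0.350, and with the macrophage covariate T cells had 0.0955. Genes of DNA repair (-0.17, 20 of 21 below 0), DNA replication (-0.11, 18 of 22) and stress response (-0.28, 15 of 18) fell as lists, and the DNA repair call ended with muscle and fat (0.350) or macrophage (0.102) covariates and that of DNA replication with the macrophage covariate (0.145). Irf7 was at 55.0 ± 19.8 CPM against 25.7 ± 2.13 in controls (n = 3, log2 fold change 1.09 ± 0.27) and was the 1 interferon gene higher when adjusted over the list alone. Likewise Lum (0.99 ± 0.27) and Col6a3 (0.47 ± 0.13) were higher among the fibroblast genes, and among the p53 targets Btg2 was higher (1.13 ± 0.29) and Zmat3 lower (-0.55 ± 0.10). Cdkn1a (0.18 ± 0.21), Cd274 (0.17 ± 0.31) and Cd8a (0.24 ± 0.55) did not pass. Over all genes edgeR called 0, with 1319 at an unadjusted p below 0.05 and a smallest adjusted p of 0.489. DESeq2 called 67 (39 higher, 28 lower), limma on FPKM called 0, and the authors' deposited table called 47 (36 higher, 11 lower). Also higher when adjusted over the list alone were 14 of 18 muscle and 2 of 13 fat markers, in a group whose replicate 2 held the largest muscle share. By camera with a preset correlation the adjusted p values were 7.64e-13 for type I interferon, 0.000195 for T cells, 0.000221 for macrophages and DNA repair, 1.99e-06 for fibroblasts, 0.00475 for DNA replication and 0.000233 for stress response. The lists of interferon gamma (0.000523), checkpoints (0.0306), chemokines (0.0496), muscle (9.04e-06) and fat (3.85e-05) also rose, and the red cell list fell (0.00301). With muscle and fat covariates interferon gamma was at -0.014 (0.692) and chemokines at -0.35 (0.840), and with the macrophage covariate checkpoints were at -0.036 (0.510) and chemokines at -0.12 (0.979), and interferon gamma (0.510) and muscle (0.102) lost their calls. The checkpoint call also ended with muscle and fat covariates (0.147) and with the GC and length trend removed (0.0642), and the chemokine call with that trend removed (0.131) and with the replicate block (0.0898). Without the 4 muscle-rich libraries the calls of checkpoints (0.0796), chemokines (0.0835), macrophages (0.0600) and DNA replication (0.0796) ended. Without control replicate 1 the calls ended for T cells (0.426), macrophages (0.424), interferon gamma (0.521), checkpoints (0.747), chemokines (0.961) and DNA replication (0.135), and the number of changed lists fell from 13 to 8. Without RT replicate 2 it fell to 7, with macrophages at 0.070, chemokines at 0.070, checkpoints at 0.0907, DNA replication at 0.0798, red cells at 0.070 and muscle at 0.231. Without RT replicate 1 the call of fat (0.638) and that of red cells (0.081) ended. The fibroblast and chemokine lists had mean changes, relative to all other genes, of -0.08 and -0.13. Camera still called both higher there (adjusted p = 0.0473 and 0.0276), with 12 of 20 and 16 of 22 genes above 0. Without RT replicate 3 checkpoints (0.128), chemokines (0.191) and DNA replication (0.0905) lost theirs, and without control replicate 2 the red cell list did (0.0524).

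RT+MEKi was set against RT to ask what the drug added to radiation. With the drug added the type I interferon list rose further, with all 22 genes above 0 and a mean log2 fold change of 0.62, and 13 of them were higher when adjusted over the list alone. This and the other 13 list calls here, by camera with a preset correlation, were lost with an estimated one (adjusted p from 0.263 to 0.791). At least as many lists were called in 6 of 10 splits of these libraries, the real one included. Ifit3 went from 22.5 ± 8.65 to 48.4 ± 10.8 CPM (n = 3, log2 fold change 1.10 ± 0.33) and Rsad2, an antiviral enzyme, from 27.6 ± 4.11 to 58.8 ± 5.28 CPM (1.09 ± 0.24). Macrophage markers (mean 0.44) and T cell markers (0.62) rose as lists, Ccr2 was higher when adjusted over the list alone (1.03 ± 0.23), and the DNA repair genes fell as a list (-0.17, 21 of 21 below 0). With the macrophage covariate DNA repair turned to 0.10 relative to all other genes (adjusted p = 0.789), and T cells lost their call (0.754). Among fibroblast genes Lum (0.94 ± 0.26) and Pdgfra (0.39 ± 0.12) were higher and Acta2, a smooth muscle actin, lower (-1.28 ± 0.33) when adjusted over the list alone, and among B lineage genes Blk was higher (3.14 ± 0.76). Over all genes edgeR called 0, with 1075 at an unadjusted p below 0.05, DESeq2 called 41, limma on FPKM called 3, and edgeR without a filter on low counts called 1. The nearest gene was Ifit2 (0.96 ± 0.12, edgeR adjusted p = 0.0780). Dusp6 (-0.18 ± 0.14), Cd274 (0.17 ± 0.31) and Cd8a (0.04 ± 0.55) did not pass. By camera with a preset correlation the adjusted p values were 3.51e-29 for type I interferon, 1.12e-07 for macrophages, 3.42e-05 for T cells and 8.34e-05 for DNA repair. The fat list rose (2.89e-08) and the red cell list fell (1.04e-07, with 6 of 7 lower when adjusted over the list alone). The lists of MHC class II (0.0271), interferon gamma (0.0207) and B lineage genes (0.0209) also rose, and those of ERK output (0.0267), neutrophils (0.0196), endothelium (0.0150), mitotic genes (0.0498) and DNA replication (0.00406) fell. With the macrophage covariate MHC class II (0.000645) and interferon gamma (0.000166) were lower instead, and endothelium (0.419), mitotic genes (0.564) and DNA replication (0.542) changed sign. With the red cell covariate neutrophils were higher (3.72e-06), and ERK output (0.750) and endothelium (0.298) changed sign. An estimated correlation was not run with covariates, so these opposite calls are uncertain. The B lineage call ended with muscle and fat (0.279), macrophage (0.247) and red cell (0.167) covariates. Relative to all other genes that list was then at 0.67, 0.56 and 0.58, in that order. The muscle and fat covariates also ended those of MHC class II (0.285), interferon gamma (0.705), ERK output (0.230), neutrophils (0.880) and endothelium (0.229). The red cell covariate did so for MHC class II (0.910) and interferon gamma (0.0856), and the macrophage covariate for ERK output (0.167) and neutrophils (0.106). Without the 4 muscle-rich libraries interferon gamma (0.600), mitotic genes (0.536) and DNA replication (0.0726) lost theirs. Without RT replicate 3 the calls of ERK output (0.379), MHC class II (0.466), interferon gamma (0.0658), B lineage (0.0761), neutrophils (0.305) and endothelium (0.564) ended, and without RT replicate 1 those of mitotic genes (0.637) and DNA replication (0.273). Without RT+MEKi replicate 1 the lists of ERK output (0.0595), MHC class II (0.191), interferon gamma (0.644), mitotic genes (0.975) and DNA replication (0.403) lost theirs. Without RT+MEKi replicate 2 ERK output (0.0735) and neutrophils (0.216) did, and without RT+MEKi replicate 3 B lineage (0.194), neutrophils (0.207) and endothelium (0.207).

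RT+MEKi was set against MEKi to ask what radiation added to the drug. Mxd4, a transcriptional repressor of the MYC network (gene ID 17122, chromosome 5, 34173890 to 34187710), was the 1 gene that edgeR called, rising from 11.8 ± 0.772 to 22.8 ± 2.24 CPM (n = 3, log2 fold change 0.95 ± 0.11, adjusted p = 0.0489). It was lost when any of the 6 libraries was left out, and with DESeq2 size factors, without a filter on low counts and with only the 2 compared groups in the fit. The filter at a mean CPM of 5, the replicate block, the muscle and fat or macrophage covariates and removal of the GC and length trend also ended it. It was kept with library totals, the DESeq2 test, limma on FPKM and the red cell covariate. At an unadjusted p below 0.05 there were 2049 genes, DESeq2 called 414 and limma on FPKM 12. Type I interferon genes rose as a list, with 22 of 22 above 0, a mean log2 fold change of 0.69 and 16 higher when adjusted over the list alone, among them Irf7 (1.26 ± 0.27) and Cmpk2 (1.00 ± 0.16). This and the other 11 list calls here, by camera with a preset correlation, lapsed with an estimated one (adjusted p from 0.388 to 0.801). At least as many lists were called in 5 of 10 splits of these libraries, the real one included. Macrophage markers (mean 0.62), T cell markers (0.82) and fibroblast genes (0.54) rose as lists, and the fibroblast list was at -0.78 relative to all other genes with the macrophage covariate (adjusted p = 0.669) and had an adjusted p = 0.0796 with muscle and fat covariates. Adjusted over the list alone, Ly6c2 (1.27 ± 0.33), Ccr2 (1.00 ± 0.23), Lum (1.11 ± 0.27), Col5a1 (0.68 ± 0.19) and Pdgfra (0.44 ± 0.12) were higher. So were the checkpoint genes Lgals9 (0.66 ± 0.18) and Vsir (0.64 ± 0.18) and the B lineage gene Blk (2.97 ± 0.76), with Pdgfra the 1 receptor tyrosine kinase gene. Genes of cholesterol synthesis (-0.25, 16 of 18 below 0), DNA repair (-0.23, with 3 lower when adjusted over the list alone) and stress response (-0.27) fell as lists. Relative to all other genes DNA repair turned to 0.13 (0.842) and stress response to 0.083 (0.976) with the macrophage covariate, and T cells lost their call (0.929). The stress response call also ended with the red cell covariate (0.124). Without the 4 muscle-rich libraries, which left 1 MEKi library, the calls of cholesterol synthesis, stress response, DNA replication and muscle ended. Relative to all other genes these lists were then at -0.26, -0.39, -0.20 and -1.04, in that order. By camera with a preset correlation the adjusted p values were 2e-24 for type I interferon, 3.18e-10 for macrophages, 4.19e-06 for T cells, 2.86e-05 for fibroblasts, 0.000103 for cholesterol synthesis, 1.43e-05 for DNA repair and 0.0142 for stress response. The lists of interferon gamma (0.00526), checkpoints (0.0385) and fat (0.000586) rose and those of DNA replication (0.0216) and muscle (0.0385) fell. With the macrophage covariate the interferon gamma list was lower instead (0.000108), and checkpoints (0.702), DNA replication (0.976) and fat (0.929) changed sign. That lower call is uncertain, as an estimated correlation was not run with covariates. The checkpoint call ended with the red cell covariate too (0.0658), and the muscle call with the GC and length trend removed (0.0558). Without MEKi replicate 2 the calls of interferon gamma (0.415), checkpoints (0.159), DNA replication (0.056) and fat (0.101) ended, and without RT+MEKi replicate 1 those of interferon gamma (0.185), checkpoints (0.0597) and DNA replication (0.491). Without RT+MEKi replicate 3 those of checkpoints (0.146) and stress response (0.0516) did. The muscle list lost its call without MEKi replicate 1 (0.113), MEKi replicate 3 (0.627), RT+MEKi replicate 2 (0.247) or RT+MEKi replicate 3 (0.455).

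The interaction asked whether the 2 treatments together differed from the sum of their single effects on the log2 scale. Type I interferon genes lay above the sum, with 19 of 22 interaction terms above 0 and a mean of 0.24, and so did macrophage markers (mean 0.30, 19 of 20). Cholesterol synthesis genes lay below it, with 16 of 18 below 0 and a mean of -0.31, and mitotic genes did too (-0.14, 16 of 20), as did the muscle markers. By camera with a preset correlation the adjusted p values were 0.00184, 0.0189, 2.66e-05, 0.0440 and 9.99e-11 in that order, and with an estimated correlation each was 1.00. All 100 groupings of the libraries, the real one included, called at least the real 5 lists, so chance was not excluded. No single gene passed in edgeR, with 0 called, 973 at an unadjusted p below 0.05 and a smallest adjusted p of 0.489, against 32 called by DESeq2 (8 higher, 24 lower) and 0 by limma on FPKM. The smallest p values were those of Nol4l (-0.90 ± 0.15) and Cox6c (-0.74 ± 0.12), and the interaction terms of Cd274 (0.15 ± 0.44), Cd8a (0.58 ± 0.79) and Dusp6 (0.11 ± 0.20) lay within 1 SE of 0. Adjusted over the list alone, the p53 target Zmat3 was higher (0.79 ± 0.14). The interferon call ended without control replicate 2 (adjusted p = 0.0554), MEKi replicate 2 (0.461) or RT replicate 3 (0.111), and with the macrophage covariate (0.241). The macrophage call ended without control replicate 2 (0.106), control replicate 3 (0.327), MEKi replicate 2 (0.20), RT replicate 3 (0.455) or RT+MEKi replicate 1 (0.334). The mitotic call ended without control replicate 2 (0.335) or 3 (0.146), MEKi replicate 1 (0.0666) or 2 (0.426), RT replicate 1 (0.807) or RT+MEKi replicate 1 (0.621), and the list turned to 0.13 with the macrophage covariate (0.366) and to 0.0016 with the red cell covariate (0.124). The number of changed lists moved from 5 to 9 without control replicate 1, 2 without control replicate 2, 3 without MEKi replicate 2 and 8 without RT replicate 2.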

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

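Chosen after the result was seen were the tests with covariates, with a floor on the muscle counts, of muscle and fat shares, of the macrophage list, of GC content and transcript length, and of the interferon list without control replicate 1. The interaction terms of 5 lists passed the test of a difference between the effect of a treatment with and without the other: type I interferon with a mean of 0.24, macrophages 0.30, mitotic genes -0.14, cholesterol synthesis -0.31 and skeletal muscle -8.27. Each had an adjusted p = 1.00 with an estimated correlation. For muscle the fitted terms depend on near-empty controls: 1 of 18 markers, Pvalb, had 0 counts in all controls, and the median over the list was -8.34, also with that gene at a floor of 3 counts over the group. A floor on 1 of 18 values can hardly move a median, so this does not test that dependence. Cholesterol synthesis was higher with MEKi alone (mean 0.25), near 0 with RT alone (0.07, not past the threshold) and at 0.00 with both. The MEKi rise had an adjusted p = 0.814 with an estimated correlation, and turned to -0.15 relative to all other genes with the red blood cell covariate (0.727). Leaving out MEKi replicate 2 gave the interferon list an adjusted p = 0.461, control replicate 2 gave 0.0554, RT replicate 3 gave 0.111 and the macrophage covariate gave 0.241. Of 100 groupings, the real one included, all had at least the real 5 changed lists, and the highest other had 22, so chance was not excluded for the lists of the interaction. For genes the real count was 0, which any grouping reaches, so that count decides nothing, and the highest other was 1.

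The type I interferon list rose in RT+MEKi against control. With muscle and fat markers as covariates the rise was 0.519 with an SE of 0.155, against 1.08 with an SE of 0.202 without them. Part of its size thus went with them. The fat list mean was itself 4.48 log2 CPM in RT+MEKi against -0.617 in control, and few tumours set its slope. That fit therefore cannot exclude fat tissue as the source. Without the 4 muscle-rich libraries the rise was 1.01, which argues against muscle tissue as the whole source. A low control replicate 1 was argued against by the rise of 0.977 with an SE of 0.226 without it. With the macrophage markers as a covariate the rise was 0.697 with an SE of 0.245. These markers were themselves higher in RT+MEKi by 0.81 with an SE of 0.27, and few tumours per group set their slope. That fit therefore cannot exclude more macrophages as the whole source. They stay open as a part or the whole of it, since the interferon list rose by 0.268 more than the macrophage list, with an SE of 0.212. These data could reflect interferon signalling in tumour cells, in infiltrating cells or in both, and the bulk libraries do not separate them.

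Muscle and fat transcripts stood out in some pieces. All 18 of 18 muscle markers had the same 4 highest libraries, MEKi replicates 1 and 3, RT replicate 2 and RT+MEKi replicate 1. These 4 were picked by the share of counts of the same markers, so this adds little to the shares themselves. Muscle tissue carried along would give such a pattern, but this does not test it. A treatment effect in every treated tumour was argued against, since 4 of 9 treated libraries were over 3 times the highest control. No control was among the 4, so an effect in some tumours stays open. For fat, 3 of 3 RT+MEKi libraries and 2 of 6 MEKi or RT libraries were over 3 times the highest control, and MEKi replicate 3 (0.0309%) and RT replicate 2 (0.0354%) also lay above all controls, so tissue carried along and a treatment effect cannot be told apart.

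For the 428 genes changed in RT+MEKi against control, GC content and transcript length as the whole source were argued against, since 404 stayed past the threshold once the trend of each library was removed. With muscle and fat covariates the median change in each gene's own direction was 0.482 with a median SE of 0.162, against 0.59 with an SE of 0.121 in the reported fit, and without control replicate 1 it was 0.562 with an SE of 0.135. The lower quartiles of 0.351 and 0.428 were over 2 median SE above 0, which goes against that tissue or a low control replicate 1 as the whole source. The genes were picked for their change in these same libraries, which favours such a result. Fat markers were also higher in RT+MEKi, so few tumours set their slope. Neither explanation is therefore excluded. In both fits all 428 kept their direction and 0 stayed past the threshold, as the SE grew and the size fell. With the macrophage covariate the median was 0.405 with an SE of 0.159, and with the red blood cell covariate 0.472 with an SE of 0.1996, again with 428 in the same direction and 0 past the threshold. The lower quartiles of 0.311 and 0.340 were less than 2 median SE above 0. More macrophages and less blood in the RT+MEKi pieces therefore stay among the open explanations, with the treatments themselves. The 10 splits of 6 samples cannot give a share under 0.05, and the real split gave 428 genes and the highest other 0.

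The same limit of 10 splits holds for the other comparisons, and a real count of 0 genes is reached by any split. In RT+MEKi against MEKi the real split gave 1 gene and 12 lists, and the highest others 0 and 18, with 1 and 5 of 10 splits as large. In MEKi against control the real split gave 0 genes and 10 lists, the highest others 0 and 21, with 10 and 7 splits as large. In RT+MEKi against RT the values were 0 and 14, the highest others 0 and 16, with 10 and 6 as large. For the lists of RT+MEKi against control the real split gave 17 and the highest other 21, with 7 as large. In RT against control it gave 0 genes and 13 lists, with 10 and 10 as large. The highest other there, 21 genes and 21 lists, set control replicates 1 and 2 with RT replicate 3 against the rest. Those 3 have the largest shares of red blood cell transcripts among these 6 libraries. This was seen after that split stood out, and whether its genes follow blood content was not tested.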

How the results depend on the processing

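Most alternatives were fixed before the data were examined, and those with marker covariates, without the 4 muscle-rich libraries or with the GC and length trend removed were chosen after seeing the data. A list value here is the mean log2 fold change of a list minus that of all other tested genes. Of 867 values of single genes under alternatives fixed in advance, 606 kept their direction and side of the threshold, 228 kept the direction and fell short of it, 4 now passed it and 29 changed sign. For gene lists the counts were 811, 630, 155, 0 and 26. Among values added later they were 295, 116, 140, 0 and 39 for genes and 336, 217, 73, 0 and 46 for lists. The type I interferon list of RT+MEKi against control kept its direction in each alternative and its call in each except the estimated correlation, with list values of 0.94 in the reported fit, 0.52 with muscle and fat covariates and 1.03 without control replicate 2. Depth limits genes of low count, such as Adipoq and Plin1 at 1 and 0 counts in each control. The cause of the shifts given here was not tested, except that fits of fewer libraries or more terms have fewer residual degrees of freedom.

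With an estimated correlation, the number of changed lists was 0 in each of the 6 comparisons. With DESeq2 size factors, 0 genes changed in RT+MEKi against MEKi. With library totals as the only scaling, 3 lists changed in the interaction, and the log2 fold change of Mki67 in RT+MEKi against control was 0.052. Without a filter on low counts, the number of changed genes was 1 in MEKi against control, 268 in RT+MEKi against control, 1 in RT+MEKi against RT and 0 in RT+MEKi against MEKi. In RT+MEKi against control the list values of MHC class I and dendritic cells were then -0.028 and -0.0048. Camera still called MHC class I higher (adjusted p = 0.0325), with 15 genes above 0 and 4 below, and no longer called dendritic cells (0.0534). With a filter at a mean CPM of 5, 0 genes changed in RT+MEKi against MEKi, and Mki67 was at 0.013 in RT+MEKi against control. The DESeq2 Wald test called 165 genes in MEKi against control, 67 in RT against control, 1523 in RT+MEKi against control, 41 in RT+MEKi against RT, 414 in RT+MEKi against MEKi and 32 in the interaction. Of those 1523 genes, 423 were among the 428. With limma on log2(FPKM + 1), 1 gene changed in MEKi against control, 3 in RT+MEKi against RT and 12 in RT+MEKi against MEKi. Mki67 in RT+MEKi against control was then at 0.051 and Cd8a in RT+MEKi against RT at -0.0030. With limma on log2(FPKM + 0.1), the counts were 1, 4 and 12, and the same values were 0.052 and -0.045. A fit of only the 2 compared groups called 822 genes in RT+MEKi against control and 0 in RT+MEKi against MEKi.

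The labels give each group the replicate numbers 1 to 3. Over the 18 pairs of libraries with the same number, the correlation of their deviations from the group means lay between -0.52 and 0.48 with a median of -0.18. Of these, 5 pairs were over 0.1, and 3 of 12 libraries correlated best with a library of their own number, so the numbers were not taken to pair the samples. With the replicate block, 16 genes changed in RT+MEKi against control and 0 in RT+MEKi against MEKi, the list value of chemokines in RT against control was -0.0088 and the log2 fold change of Cd8a in RT+MEKi against RT was -0.021.

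With the 4 muscle-rich libraries left out, where MEKi is 1 library assumed to vary like the other groups, 0 genes changed in RT+MEKi against control and 0 in RT+MEKi against MEKi, and 11 lists changed in the interaction. Values that changed sign in MEKi against control were Cd274 at -0.36, MHC class I at -0.038, interferon gamma at -0.37, DNA repair at 0.18 and fat at -0.35. In RT+MEKi against control they were Cd8a at -0.074, Mki67 at 0.12, H2-K1 at -0.082, B2m at -0.053 and H2-D1 at -0.091. In RT+MEKi against RT they were Cd274 at -0.19 and Cd8a at -0.37.

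With muscle and fat covariates, 0 genes changed in RT+MEKi against control and 0 in RT+MEKi against MEKi. Then 6 lists changed in MEKi against control, 7 in RT against control, 7 in RT+MEKi against control, 9 in RT+MEKi against RT and 10 in the interaction. In MEKi against control Cd274 was at -0.12, MHC class I at -0.013, interferon gamma at -0.29 and DNA repair at 0.12. In RT against control Cdkn1a was at -0.078, interferon gamma at -0.014, chemokines at -0.35 and fibroblasts at -0.61. RT+MEKi against control gave Ifng -0.039, Dusp6 0.0012, Cdkn1a -0.25, Mki67 0.026, H2-K1 -0.051, B2m -0.13, chemokines -0.28 and fibroblasts -1.31. RT+MEKi against RT gave Cd8a -0.00044 and Dusp6 0.090.

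With the macrophage covariate, the number of changed genes was 1 in MEKi against control, 0 in RT+MEKi against control, 1 in RT+MEKi against RT, 0 in RT+MEKi against MEKi and 69 in the interaction. Then 6 lists changed in MEKi against control and 8 in RT against control. MEKi against control gave Cd274 -0.045 and MHC class I -0.0070, and RT against control gave Cdkn1a -0.0023, checkpoints -0.036 and chemokines -0.12. Among genes of RT+MEKi against control, Ifng was at -0.86, Cd274 at -0.14, Cd3e at -0.21, Cd8a at -0.85, Cdkn1a at -0.29, Mki67 at 0.29, H2-K1 at -0.51, B2m at -0.32 and H2-D1 at -0.34. Its lists gave MHC class I -0.18, interferon gamma -0.34, checkpoints -0.16, chemokines -0.37, dendritic cells -0.014, fibroblasts -0.79, endothelium 0.24 and muscle -6.51. RT+MEKi against RT gave Cd274 -0.19, Cd8a -0.87, MHC class II -0.38, interferon gamma -0.35, endothelium 0.17, mitotic genes 0.13, DNA replication 0.098 and DNA repair 0.10. Genes of RT+MEKi against MEKi gave Cd274 -0.095, Cd8a -0.18 and Cdkn1a -0.17. Its lists gave interferon gamma -0.43, checkpoints -0.092, fibroblasts -0.78, DNA replication 0.16, DNA repair 0.13, stress response 0.083 and fat -0.58. The mitotic list was at 0.13 in the interaction.

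With the erythroid covariate, 1 gene changed in RT+MEKi against control, 1 in RT+MEKi against RT and 5 in RT+MEKi against MEKi. Cholesterol synthesis was at -0.15 in MEKi against control. Dendritic cells were at -0.16, endothelium at 0.12 and stress response at 0.0041 in RT+MEKi against control. Dusp6 was at 0.011, ERK output at 0.0092, neutrophils at 0.58 and endothelium at 0.12 in RT+MEKi against RT, and mitotic genes were at 0.0016 in the interaction. With the GC and length trend removed, the number of changed genes was 1 in MEKi against control, 717 in RT+MEKi against control and 0 in RT+MEKi against MEKi. Mki67 was at 0.059, H2-K1 at -0.060, B2m at -0.013, H2-D1 at -0.072 and MHC class I at -3.87e-06 in RT+MEKi against control. Some lists were past the threshold on the opposite side of the reported call, by camera with a preset correlation. The estimated correlation was not run in these fits. Interferon gamma was lower in MEKi against control without the 4 muscle-rich libraries (adjusted p = 0.0230), and neutrophils were higher in RT+MEKi against RT with the erythroid covariate (3.72e-06). With the macrophage covariate MHC class I (0.000123), interferon gamma (0.00896), chemokines (0.0218) and muscle (3.25e-06) were lower in RT+MEKi against control. So were MHC class II (0.000645) and interferon gamma (0.000166) in RT+MEKi against RT, and interferon gamma (0.000108) in RT+MEKi against MEKi. The single genes that changed sign were past the threshold neither in the reported fit nor in the alternative.

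Leaving out 1 library at a time moved the number of changed genes between 0 and 1 in MEKi against control, where 1 came without MEKi replicate 2, and between 0 and 692 in RT+MEKi against control, where 692 came without control replicate 3 and 0 without control replicate 1 or RT+MEKi replicate 1. It was 0 each time in RT+MEKi against MEKi. The number of changed lists lay between 7 and 18 in MEKi against control, with 18 without control replicate 3, and between 7 and 18 in RT against control, with 7 without RT replicate 2. In the interaction it lay between 2 without control replicate 2 and 9 without control replicate 1. For MEKi against control the ranges were -0.22 to 0.24 for Cd274, -1.05 to 0.10 for Cd8a, -0.077 to 0.14 for MHC class I and -0.060 to 0.81 for interferon gamma. Genes of RT against control gave -0.070 to 0.39 for Cd274 and -0.14 to 0.88 for Cd8a. Its lists gave -0.0085 to 0.80 for interferon gamma, -0.12 to 0.33 for checkpoints, -0.13 to 0.55 for chemokines, -0.012 to 0.87 for T cells, -0.014 to 0.32 for macrophages and -0.079 to 0.96 for fibroblasts. For RT+MEKi against control they were -0.11 to 0.92 for Cd8a, -0.11 to 0.12 for Mki67, -0.17 to 0.17 for H2-K1, -0.048 to 0.23 for B2m, -0.11 to 0.12 for H2-D1 and -0.10 to 0.11 for MHC class I. RT+MEKi against RT ranged over -0.15 to 0.42 for Cd274, -0.31 to 0.38 for Cd8a, -1.04 to 0.14 for neutrophils, -0.61 to 0.077 for endothelium, -0.19 to 0.085 for mitotic genes and -0.21 to 0.051 for DNA replication. RT+MEKi against MEKi ranged over -0.0036 to 0.41 for Cdkn1a, -0.19 to 0.016 for DNA replication and -6.44 to 0.73 for muscle. The mitotic list ranged over -0.15 to 0.13 in the interaction.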

Other observations

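The KEGG terms were tested after the changed genes were seen. Some genes that load and make amino acids fell in RT+MEKi against control. Among the genes with a KEGG term, 121 were lower and 83 higher, and Aminoacyl-tRNA biosynthesis held 15 lower genes of 44 against 0.945 expected (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.54e-12 over 652 tests). Biosynthesis of amino acids held 11 of 58 (9.03e-06), Glycine, serine and threonine metabolism 6 of 29 (0.00314), One carbon pool by folate 5 of 18 (0.00314) and Cysteine and methionine metabolism 6 of 39 (0.0129). The genes of serine synthesis and its mitochondrial folate branch were among them. Phgdh fell from 652 ± 89.6 to 411 ± 24.3 CPM (n = 3, log2 fold change -0.66 ± 0.10, edgeR adjusted p = 0.0218) and Shmt2 from 796 ± 193 to 352 ± 42.7 CPM (-1.18 ± 0.17). Psat1 (-1.12 ± 0.17), Psph (-1.33 ± 0.21) and Mthfd2 (-1.13 ± 0.23) fell with them. Of the tRNA synthetases Gars (-0.86 ± 0.14), Yars (-0.93 ± 0.17) and Lars (-0.91 ± 0.17) fell, among others. Over all 44 members of the first term 39 log2 fold changes were below 0, with a median of -0.27. For the folate term they were 16 of 18 with a median of -0.24, and the other 3 terms had medians of -0.12, -0.09 and -0.07, with 20 of 58, 10 of 29 and 15 of 39 above 0. These enrichments rest on the 428 calls, of which 0 remained without control replicate 1 or RT+MEKi replicate 1. With muscle and fat, macrophage or red cell covariates 0 of them remained as well. Fisher's exact test takes genes as independent, which genes that vary together across 3 tumours per group are not, so its p-values are too small for such genes.

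The terms enriched among higher genes were Hepatitis C (11 of 119, adjusted p = 0.000229), Influenza A (11 of 129, 0.000385), RIG-I-like receptor signaling pathway (6 of 49, 0.00671) and Measles (8 of 120, 0.0253). Their members are mostly interferon-induced genes such as Irf7, Rsad2, Oas2 and Oas3 that the type I interferon list also holds, with Eif2ak2, a kinase activated by double-stranded RNA, at 0.44 ± 0.09. The terms share these genes with that list, so they are not an independent second result, though other members such as Akt2 and Ifngr1 lie outside it. The terms were not tested without the shared genes. They rest on the same calls, of which 0 remained without control replicate 1 or RT+MEKi replicate 1.

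The effect of a treatment without and with the other was compared over 11942 genes, between comparisons that share no library. For the drug the log2 fold changes had a Pearson r of -0.11 and a Spearman rho of 0.23, and for radiation 0.07 and 0.32, across genes, which are not independent replicates. The sign was the same for 58.2% of genes for the drug and 60.9% for radiation. The coefficients of the drug differ in sign, so no reversal of its effect can be read from them.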
